A study of Danio rerio with 10 samples.

How the data were processed

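RNA was measured in 10 libraries from sorted zebrafish (Danio rerio) pituitary cells, 5 AMCA-positive and 5 AMCA-negative. Per the labels' protocols, pituitaries were dissociated with Liberase and trypsin, dead cells were marked with propidium iodide, a 2-gate sort kept dye-positive cells apart from autofluorescent ones, and full-length cDNA was made with the SMARTer Ultra Low Input kit and 15 cycles of amplification. Groups came from the dye label of each sample. Plate and well came from the titles; plates 1 and 2 hold 4 and 6 libraries, the same sizes as the 2 sorting experiments, but the labels do not state that plate and sort are the same. Per the labels, 5 pools gave 5 AMCA-positive and 5 AMCA-negative libraries; which libraries share a pool is not given in the sources used here. Replicate numbers follow the order of the samples, so they were not used as pairs.

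The authors deposited raw gene counts, whole numbers per gene and library, as the column names say. The submitters' processing notes name cutadapt, TopHat2 2.0.13, HTSeq, DESeq2 and the build danRer10, with no role or order; the annotation and the counting settings are not given in the sources used here. The deposited normalized signal is the count divided by 1 size factor per library, and the ratio was constant within each library. The authors' deposited log2 fold changes, score (test statistic and rounded group means) and p-value columns compare AMCA-positive with AMCA-negative cells; only calls at their adjusted p-value were used, for counts beside those found here. The deposited location and type annotations of genes were used for a test of enrichment. All 14781 gene names were taken as the authors gave them: 12660 (85.7%) are current names in the RefSeq table and 14519 (98.2%) with synonyms. No mitochondrially encoded gene is listed, so the fixed list of those had no member, and 1058 genes had no count. Of 648 entries in the 31 fixed lists, 18 were found by synonym and 74 were not found.

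Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test, two-sided, plate plus group), adjusted by Benjamini-Hochberg with 0.05 as threshold. Log2 fold changes carry the error implied by the F test, written as SE. CPM is edgeR's count scaled by the TMM-adjusted library size, given as mean ± SD over 5 libraries, while shares use all counts of a library. A fold against a group with no count was computed against a floor of 3 counts over the group, and one against 1 to 3 counts is a ratio with a 95% counting interval; floors and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Lists were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of counts were tested by exact permutation with scipy 1.17.1 over 252 arrangements, two-sided, adjusted over 8 lists. The plate by group interaction was tested with the same edgeR model. Statistics were tested on simulated data with known changes: of 50 genes changed at each size in the comparison of the groups (49, 50, 50 and 49 tested), 0%, 6%, 30% and 71.4% were recovered at log2 changes of 1, 2, 4 and 8, with 1 of 9615 unchanged genes called. In the simulated interaction, 80% of 200 genes were recovered at a log2 difference of 16. Apart from the set changes, both simulated groups shared 1 level and 1 dispersion per gene. The wider spread and the missing genes of the AMCA-negative libraries were not simulated, so these rates may differ from those in the real data.

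The genes named were chosen by a rule fixed before the data were examined, as were the gene lists. The first part takes the 12 largest increases and the 12 largest decreases among genes past the test, with at least 20 CPM in the higher group, no overlap between the groups and no clone name. The second takes up to 4 members of each list with the smallest adjusted p. The third takes slc15a2, gfap, vim, cyp26b1, tgfb3, slit3, slco1c1, prl, gh1, pomca, oxt and avp where measured. The lists cover pituicyte factors from work of the same laboratory, astroglia, infundibular factors, peptide transporters, hormones, pituitary transcription factors, secretory granules, neuropeptides, neurons, oligodendrocytes, endothelium, mural cells and fibroblasts, leukocytes, red cells, epithelium and progenitors, retinoic acid, TGF-beta, FGF, angiogenic factors, axon guidance, Notch, WNT, matrix, osmoregulation, insulin-like growth factors, thyroid hormone, immediate early genes, cell cycle, cholesterol synthesis and ribosomal proteins.

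Alternatives were DESeq2 scaling and the DESeq2 1.42.0 Wald test, TMM without hormone genes, no filter, a filter of 10 CPM in 5 libraries, limma-voom with quality weights, no plate term, neighbouring wells as a block, each plate alone, and leaving out each library. Chosen after seeing the data were leaving out negative replicates 1 and 3 together, scaling from genes outside the red cell list, upper quartile scaling and library size alone. Depth was 4250948 to 6068781 counts per library; the biological coefficient of variation was 1.13, and a log2 change of 2 was recovered for 6% of simulated genes.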

Results

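Messenger RNA was profiled from cells of the adult zebrafish pituitary that had been sorted by uptake of a fluorescent dipeptide. β-Ala-Lys-Nε-AMCA is a dipeptide carrying the blue dye aminomethylcoumarin, and male fish of the TL strain, 12 months old, received 10 µL of it at 4.6 mM. Pituitaries were taken 3 hours later, 5 pools of 7 were dissociated, and cells inside the dye gate (AMCA-positive) and outside it (AMCA-negative) were collected in 2 separate sorting experiments. The labels name the AMCA-positive cells pituicytes, the astroglia of the neurohypophysis, and the AMCA-negative cells non-pituicytes. Each group had 5 libraries, 2 on plate 1 and 3 on plate 2.

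Totals ran from 4250948 to 6068781 counts per library, with an SD of 315501 among AMCA-positive and 716439 among AMCA-negative libraries (n = 5 each). At least 1 count was found for 11586 ± 188 genes in AMCA-positive and 8326 ± 757 genes in AMCA-negative libraries (SD, n = 5). The 10 most counted genes took 10.4 ± 1.26% of AMCA-positive and 33.5 ± 7.84% of AMCA-negative counts (SD, n = 5). Log2 CPM (counts scaled to one library size) correlated across genes with a median r of 0.86 between AMCA-positive libraries, 0.65 between AMCA-negative libraries and 0.51 between a library of each group. Genes are not independent replicates in these values.

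The first comparison asked which genes distinguish the dye-taking cells from the other sorted cells. In AMCA-positive cells 15 of 21 astroglial, 17 of 18 infundibular, 11 of 17 retinoic acid and 12 of 18 matrix genes tested were higher, as were 19 of 26 leukocyte, 10 of 14 mural and fibroblast and 15 of 22 immediate early genes. All 10 red cell genes were lower. With an estimated correlation, limma camera gave adjusted p = 0.0432 for the matrix and 0.0432 for the mural and fibroblast list. The others did not pass: adjusted p = 0.0811 with an estimated correlation for astroglia, 0.0602 infundibular, 0.0811 retinoic acid, 0.153 leukocyte, 0.245 immediate early and 0.0602 red cell. Of 10468 genes tested, 1693 were higher and 687 lower in AMCA-positive libraries (edgeR quasi-likelihood test with plate as a term, Benjamini-Hochberg adjusted p under 0.05, n = 5 per group). Changes of at least 2-fold made up 1685 of the higher and 621 of the lower genes. Every AMCA-positive library lay above every AMCA-negative one for 1460 of the higher genes, and below for 513 of the lower genes. With a filter of 10 CPM in 5 libraries the balance turned, to 676 higher and 742 lower of 6505 genes tested. In 398 of the higher genes no AMCA-negative library had a count, and in 5 of the lower genes no AMCA-positive library had one.

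The gene with the largest fitted increase was pcolcea, which encodes an enhancer of procollagen processing, at 173 ± 126 CPM in AMCA-positive libraries and no count in AMCA-negative ones (SD, n = 5), at least 1316-fold higher. Next came slc1a3a, a glutamate transporter gene of astroglia, at 169 ± 49.2 CPM against no count, at least 1258-fold higher. Against no AMCA-negative count stood also pglyrp5, a peptidoglycan recognition protein gene, at least 1091-fold higher, stoml3b at least 495-fold, steap4 at least 480-fold, pttg1ipb at least 482-fold and the keratin gene krt5 at least 470-fold higher. All 5 AMCA-positive libraries had more pglyrp5 than any AMCA-negative one, but one of them held 627 CPM and the next 46.4. The level of krt5 likewise rested largely on positive replicate 4, at 228 CPM with the next at 31.5, and its bound with it. The collagenase gene mmp13a had 1 AMCA-negative count and a ratio of 5852-fold (95% counting interval 1050 to 231167), and the transcription factor gene cebpa had 2 and a ratio of 4715-fold (95% counting interval 1305 to 38934). The complement gene c1qb rose by 11.44 ± 0.62 on the log2 scale (SE, n = 5 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.16e-06), from 0.812 ± 0.523 to 2277 ± 819 CPM (SD). For lgals3bpb the log2 fold change was 11.42 ± 0.64 (SE; edgeR adjusted p = 1.19e-06), and for the coagulation factor XIII gene f13a1a.1 it was 11.31 ± 1.34 (SE; edgeR adjusted p = 2.25e-04). AMCA-positive libraries were also uneven in mmp13a (10.4 to 658 CPM), steap4 (4.54 to 168) and f13a1a.1 (70.0 to 3300). Bounds and counting intervals do not cover that spread.

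Genes of the red cell lineage were among those with the largest decreases. First in the ranking of decreases was the transcription factor gene tal2, with a log2 fold change of -10.93 ± 1.00 (SE, n = 5 per group, edgeR adjusted p = 3.16e-05). Of red cell genes, the erythropoietin receptor gene epor had one of -9.87 ± 0.69 (edgeR adjusted p = 3.84e-06). The gene alas2, which encodes the first enzyme of haem synthesis in red cells, had one of -9.60 ± 0.56 (edgeR adjusted p = 1.58e-06). Levels of alas2 were 5.72 ± 4.81 CPM in AMCA-positive and 4088 ± 1159 CPM in AMCA-negative libraries (SD, n = 5). The beta globin genes ba1 and ba1l had log2 fold changes of -9.07 ± 0.51 and -8.97 ± 0.50 (SE), with ba1l at 97.4 against 48407 CPM. Globin genes form a family of similar copies among which reads could be split, so the level of each is uncertain. The remaining genes of the same ranking were hif1al2 (-10.77 ± 0.52), nt5c2l1 (-10.57 ± 0.50), rfesd (-9.49 ± 0.88), nmt1b (-9.15 ± 1.32) and the blood group gene rhd (-9.10 ± 0.82), as log2 fold changes with SE. The lipoxygenase gene alox5b.3 had no AMCA-positive count and was at least 428-fold lower, and the apelin receptor gene aplnrb had 3, with a ratio of 489-fold (95% counting interval 167 to 2375) toward AMCA-negative.

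**Figure D1:**
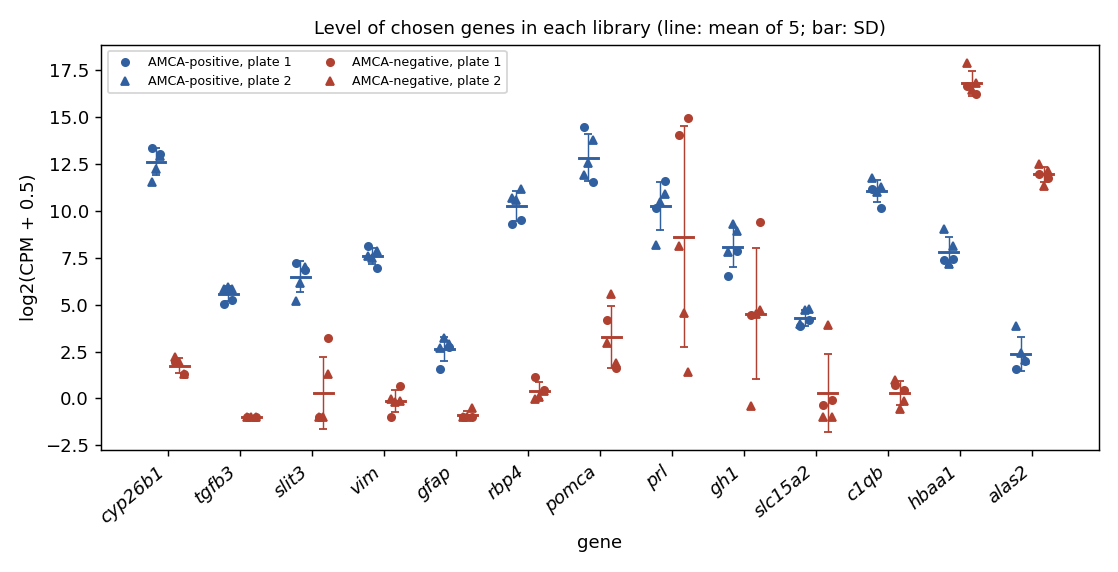
The vertical axis is log2(CPM + 0.5) of each library, with circles for plate 1, triangles for plate 2, a line at the mean and a bar for the SD of 5 libraries. The AMCA-positive libraries sit above every AMCA-negative library for cyp26b1, tgfb3, slit3, vim, gfap, rbp4, pomca and c1qb and below them for hbaa1 and alas2, while prl, gh1 and slc15a2 overlap.

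Pituicyte factors named in later work of the same laboratory, as recalled without a source at hand, were cyp26b1, tgfb3 and slit3. All 3 were higher by edgeR, 3 of 3 also when adjusted over the list alone, and 2 of 3 by limma-voom with quality weights. Since they were chosen on these samples this is not independent evidence. The retinoic acid-degrading enzyme gene cyp26b1 reached 6970 ± 3032 CPM against 2.98 ± 0.963 (SD, n = 5), a log2 fold change of 11.12 ± 0.49 (SE; edgeR adjusted p = 4.66e-07). The growth factor gene tgfb3 was at 48.5 ± 12.6 CPM with no AMCA-negative count, at least 365-fold higher, and the guidance ligand gene slit3 had a log2 fold change of 5.99 ± 1.42 (SE; edgeR adjusted p = 0.0113). The list passed limma camera with a Benjamini-Hochberg adjusted p of 0.0151, and had an adjusted p = 0.107 with an estimated correlation.

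Among astroglial and radial glial markers, 15 of 21 tested genes rose and none fell, and 17 rose when adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 1.55e-07; adjusted p = 0.0811 with an estimated correlation). The intermediate filament genes vim and gfap were both higher, vim by 8.64 ± 0.71 on the log2 scale (SE; edgeR adjusted p = 1.41e-05) and gfap, at 6.11 against 0.0399 CPM, with a ratio of 137-fold (95% counting interval 24.3 to 5448). The connexin gene cx43 (10.71 ± 0.79), the prostaglandin D synthase gene ptgdsb (10.55 ± 0.71) and the fatty acid-binding protein gene fabp7a (10.39 ± 0.77) were among the members with the smallest p (log2 fold change, SE), and the Notch target gene her6 had a ratio of 1800-fold (95% counting interval 616 to 8730). Of the transcription factors and signals of the infundibulum and ventral hypothalamus, 17 of 18 tested rose, 17 also adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 6.93e-09; adjusted p = 0.0602 with an estimated correlation). They included sox3 at 136 against 0.0490 CPM, six6a at 85.8 against 0.145, tbx2a at 134 against 0.319 and nkx2.1, a determinant of the ventral forebrain, at 29.7 against 0.0490. In the same libraries leukocyte markers took 2.57 ± 0.749% of AMCA-positive and 0.134 ± 0.0897% of AMCA-negative counts, red cell markers 0.0715 ± 0.0379% and 24.98 ± 6.91%, and immediate early genes 5.09 ± 0.660% and 1.02 ± 0.501% (SD, n = 5).

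The oligopeptide transporter gene slc15a2, a carrier for dipeptides, did not pass the test: its level was 19.9 ± 6.05 CPM in AMCA-positive and 3.08 ± 6.49 in AMCA-negative libraries (SD, n = 5). Its log2 fold change was 3.32 ± 1.66 (SE; edgeR adjusted p = 0.197). Negative replicate 4 held 14.7 CPM and the next AMCA-negative library 0.439. Without that library slc15a2 passed (log2 fold change 6.81, edgeR adjusted p = 0.00876). With limma-voom and quality weights on all libraries it also passed (log2 fold change of slc15a2 5.17, limma adjusted p = 0.00876). Among the named genes that setting gained 7 calls and lost 9. With edgeR on all libraries neither it nor slc15a4 passed (slc15a4: edgeR adjusted p = 0.846). These were the 2 tested members of the peptide transporter list, 0 of which passed when adjusted over the list alone and 0 had an unadjusted p under 0.05 by edgeR.

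Among genes of endocrine cells, the precursor gene pomca was higher and prolactin and growth hormone genes did not pass the test. Of 10 hormone genes tested, 2 were higher, 2 also adjusted over the list alone: pomca, the precursor of melanocyte-stimulating and adrenocorticotropic hormone, and its paralog pomcb (limma camera Benjamini-Hochberg adjusted p = 0.882; adjusted p = 0.943 with an estimated correlation). The level of pomca was 9901 ± 8311 CPM against 15.8 ± 18.8 (SD, n = 5), a log2 fold change of 9.31 ± 1.16 (SE; edgeR adjusted p = 3.29e-04), and pomcb had 2.52 against 0.0399 CPM. The prolactin gene prl averaged 1585 ± 1047 CPM in AMCA-positive and 9868 ± 14348 in AMCA-negative libraries (SD), with a fitted log2 fold change of the other sign, 1.46 ± 2.17 (SE; edgeR adjusted p = 0.712). The log2 fold change of prl was -3.67 within plate 1 and 3.60 within plate 2, neither past the test. The growth hormone gene gh1 did not pass either (2.83 ± 1.87 SE on the log2 scale; edgeR adjusted p = 0.343), but it did without negative replicate 2 (log2 fold change 4.19, edgeR adjusted p = 0.0182). Pituitary transcription factors, 15 of them tested, did not pass as a list (limma camera Benjamini-Hochberg adjusted p = 0.966). Secretory granule genes had 2 of 10 higher, 1 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.406). They were the prohormone convertase gene pcsk1, at 4.55 CPM with no AMCA-negative count, at least 34.1-fold higher, and chga (6.63 ± 2.16 SE on the log2 scale; edgeR adjusted p = 0.0474). Leaving out 1 library ended the chga call in 7 cases (negative replicates 1, 3, 4 and 5 and positive replicates 3, 4 and 5; edgeR adjusted p from 0.0534 to 0.107). The camera direction was down, without passing, for the hormone, pituitary transcription factor and neuron lists. Their median edgeR log2 fold changes were 2.17, 0.82 and 0.69, the same with floors for genes without counts. Camera compares voom values of a list with those of the other genes. The edgeR median of all genes tested was 0.69, so these medians do not show lists that rose less than other genes. The limma fry test asks whether a list moves against no change, and it passed 23 of 28 lists, 21 of them up. An upward result by fry is therefore not particular to a list. It gave the direction up for pituitary transcription factors (fry Benjamini-Hochberg adjusted p = 0.0130) and secretory granule genes (0.0237). The fry test did not pass for hormone (0.0971) and neuron lists (0.0971).

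With all libraries none of 11 neuronal genes tested passed edgeR, adjusted over the list alone or not, and 0 had an unadjusted p under 0.05 (limma camera Benjamini-Hochberg adjusted p = 0.739), and the hypothalamic neuropeptide genes had too few counts to be tested. Without 1 library 1 neuronal gene was higher in 6 of 10 cases, and 1 of 17 was with no filter. The oxytocin gene oxt had 6 counts, all in positive replicate 4, and none in AMCA-negative libraries, and the vasotocin gene avp 0 and 1. Oligodendrocyte and myelin genes had 1 of 6 tested higher, 1 adjusted over the list alone, mpz with a ratio of 712-fold (95% counting interval 128 to 28149) and overlapping groups (limma camera Benjamini-Hochberg adjusted p = 0.736). Without positive replicate 2 mpz had an edgeR adjusted p of 0.0872, and without negative replicate 2 the claudin gene cldnk passed (log2 fold change 7.55, edgeR adjusted p = 0.0271), for 2 of 8 tested higher. The thyroid hormone and prostaglandin carrier gene slco1c1 was left out by the filter, with 9 AMCA-positive and 183 AMCA-negative counts, 182 of the latter in negative replicate 2.

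Markers of further cell types rose with the astroglial genes. Pericyte, smooth muscle and fibroblast markers had 10 of 14 tested higher, 10 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 2.86e-05; adjusted p = 0.0432 with an estimated correlation). Among them were the collagen gene col1a1a (119 against 0.0753 CPM), mgp (66.8 against 0.140), tagln (33.6 against 0.0889) and lum (21.2 against 0.0399). Of 26 microglia, macrophage and other leukocyte markers, 19 rose, and 22 rose and 1 fell when adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 3.46e-04, and 0.153 with an estimated correlation). By limma-voom with quality weights 13 of the 26 rose and 1 fell. The complement gene c1qa was at 338 ± 125 against 0.223 ± 0.147 CPM (SD, n = 5), mfap4 at 608 ± 640 against 0.424 ± 0.715 and apoc1l at 250 against 0.143. Endothelial markers had 5 of 16 higher, 5 adjusted over the list alone, including erg, pecam1, flt4 and sox7 (limma camera Benjamini-Hochberg adjusted p = 0.0455; adjusted p = 0.245 with an estimated correlation). Here pecam1 was at 15.7 against 0.120 CPM. Without 1 library the endothelial list no longer passed in 7 of 10 cases, those without negative replicates 2, 3 or 4 or positive replicates 1, 3, 4 or 5 (limma camera Benjamini-Hochberg adjusted p from 0.0504 to 0.109). Epithelial and progenitor markers had 8 of 13 higher, 9 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.00460; adjusted p = 0.230 with an estimated correlation). Here krt4 was at 247 against 0.485, anxa1a at 818 against 17.7 and the chemokine gene cxcl14 at 1905 against 53.6 CPM. All 10 red cell markers fell, 10 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 3.78e-14; adjusted p = 0.0602 with an estimated correlation). The globin gene hbaa1 was at 258 against 124869 CPM.

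Genes of several signalling pathways were higher in AMCA-positive cells, in libraries that also held the leukocyte, fibroblast and endothelial markers above. For FGF ligands, receptors and targets 14 of 21 rose, 15 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 1.04e-06; adjusted p = 0.0203 with an estimated correlation). The feedback inhibitor gene spry4 stood at 119 ± 11.7 against 0.361 ± 0.472 CPM (SD, n = 5), the target genes etv4 at 125 against 0.157 and etv5a at 131 against 1.16, and spred1 at 51.9 against 0.0439. Matrix proteases and their inhibitors had 12 of 18 higher, 14 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 1.34e-05; adjusted p = 0.0432 with an estimated correlation). Among them were the gelatinase gene mmp2 at 190 against 0.202, mmp14b at 178 against 0.113 and the inhibitor gene timp2b at 125 against 0.440 CPM. Of the genes of retinoic acid synthesis, breakdown and reception, 11 of 17 rose, 12 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 1.60e-04; adjusted p = 0.0811 with an estimated correlation). Besides cyp26b1 they held the binding protein genes crabp1a at 8959 ± 4596 against 68.0 ± 76.8 CPM (SD), rbp4 at 1364 ± 690 against 0.884 ± 0.478 and crabp2b at 22.7 against 0.0563. WNT ligands and targets had 12 of 18 higher, 13 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 3.46e-04; adjusted p = 0.104 with an estimated correlation). Members with the smallest p were sfrp5 and sfrp1b, which encode secreted antagonists of WNT, at 490 and 104.6 CPM against 0.525 and 0.0490, the receptor gene fzd2 at 67.5 against 0.0399, and dkk3b, at least 215-fold higher. Notch genes had 8 of 20 higher, 10 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 6.49e-04; adjusted p = 0.144 with an estimated correlation). Here hey2 was at least 114-fold, jag1a at least 46.7-fold and her4.2 at least 120-fold higher.

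Ligands that act on blood vessels had 8 of 12 higher and 1 lower, 8 and 1 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.00460; adjusted p = 0.121 with an estimated correlation). The chemokine gene cxcl12a was at 476 ± 314 against 0.178 ± 0.106 CPM (SD, n = 5), vegfab at 41.5 ± 8.54 against 0.684 ± 1.24, angptl4 at 234 against 10.3 and pdgfaa at least 84.8-fold higher. Axon guidance genes had 6 of 16 higher, and 6 higher and 1 lower adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.0877). Higher members included nrp2b at 54.9 against 0.768, robo1 at 6.85 against 0.0399 and sema3aa at 5.25 against 0.0563 CPM. TGF-beta genes had 3 of 12 higher, 4 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.0670). Here ltbp3 was at 63.4 against 0.289 and tgfbi at 166 against 6.56 CPM beside tgfb3. Without negative replicate 1 smad3a passed as higher (log2 fold change 1.97, edgeR adjusted p = 0.0349). The tgfbi call ended without negative replicate 4 (edgeR adjusted p = 0.0566), and the TGF-beta list passed without positive replicate 4 (limma camera Benjamini-Hochberg adjusted p = 0.0360) or negative replicate 5 (0.0482). The axon guidance list passed without positive replicate 2 (limma camera Benjamini-Hochberg adjusted p = 0.0459). Insulin-like growth factor genes had 6 of 14 higher and 2 lower, 9 and 2 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.0836). The growth factor gene igf2b was at 284 ± 116 against 0.572 ± 0.943 CPM, igf2a at 28.6 against 0.132, igfbp7 at 33.5 against 0.0962, and igfbp1a fell from 1776 ± 766 to 75.8 ± 35.7 CPM (SD; edgeR adjusted p = 2.53e-05). That list passed without negative replicate 1 (limma camera Benjamini-Hochberg adjusted p = 0.0430) or positive replicate 2 (0.0354).

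Receptors and transporters linked to neurohypophyseal peptides and osmoregulation had 0 of 6 higher and 2 lower, 0 and 2 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.445). These were the water channel gene aqp1a.1, known also from red cells, at 4.77 against 1929 CPM, and the taurine transporter gene slc6a6b at 4.15 against 43.6. The list's median log2 fold change was 1.00 and its mean -0.56. Its camera direction was down. The channel gene trpv4 passed without negative replicate 5 (log2 fold change 7.75, edgeR adjusted p = 0.0128) and, with all libraries, by limma-voom with quality weights (log2 fold change of trpv4 4.14, limma adjusted p = 0.0378), and 1 member was higher without negative replicate 4. The slc6a6b call ended without negative replicate 1 or positive replicate 1, 2, 4 or 5 (edgeR adjusted p from 0.0551 to 0.0830). Thyroid hormone genes had 1 of 6 lower, 1 higher and 1 lower adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.739). The lower gene was the receptor gene thraa, at 9.76 against 101 CPM. The deiodinase gene dio1 did not pass over all genes, at 52.4 against 1.77 CPM with every AMCA-positive library above every AMCA-negative one (edgeR adjusted p = 0.0632). Negative replicate 5 held 8.58 CPM of it, and without that library it passed (log2 fold change 9.25, edgeR adjusted p = 0.00198). It also passed by limma-voom with quality weights (log2 fold change of dio1 6.96, limma adjusted p = 0.00821). The list's median log2 fold change was -4.7e-04, its mean 0.22 and its camera direction down. Proliferation genes had 5 of 21 higher and 1 lower, 6 and 1 adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.260). The higher genes included mcm3 at 10.6 against 0.0399 and mcm5 at 14.2 against 0.113 CPM. The lower gene was hmgb2a, at 365 against 1569 CPM. Cholesterol synthesis genes had 1 of 12 higher, dhcr7, and 1 lower, fdps, both with overlapping groups and none adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 0.954). Without 1 library the dhcr7 call ended in 7 cases (edgeR adjusted p from 0.0579 to 0.0825) and the fdps call in 8 (edgeR adjusted p from 0.0572 to 0.0781). Without negative replicate 2 nsdhl passed as higher (log2 fold change 8.21, edgeR adjusted p = 0.0106).

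Immediate early and heat shock genes, which tissue dissociation can induce, had 15 of 22 higher, and 19 higher and 1 lower adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 3.98e-05; adjusted p = 0.245 with an estimated correlation). The members junba, jun, junbb and gadd45ba rose by 4.15 ± 0.44, 2.33 ± 0.29, 2.14 ± 0.30 and 2.53 ± 0.30 on the log2 scale (SE, n = 5 per group), with junba at 5468 ± 813 against 309 ± 162 CPM (SD). Of 76 ribosomal protein genes tested, 42 were lower and none higher, 46 lower adjusted over the list alone (limma camera Benjamini-Hochberg adjusted p = 5.20e-32; adjusted p = 0.107 with an estimated correlation). Their median log2 fold change was -0.56, with rplp0 at 2572 ± 436 against 7192 ± 820 CPM (SD, n = 5). That decrease depended on scaling: 24 were lower and 1 higher under DESeq2 scaling and 4 lower and 2 higher, with a median of -0.06, with library size alone.

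**Figure D2:**
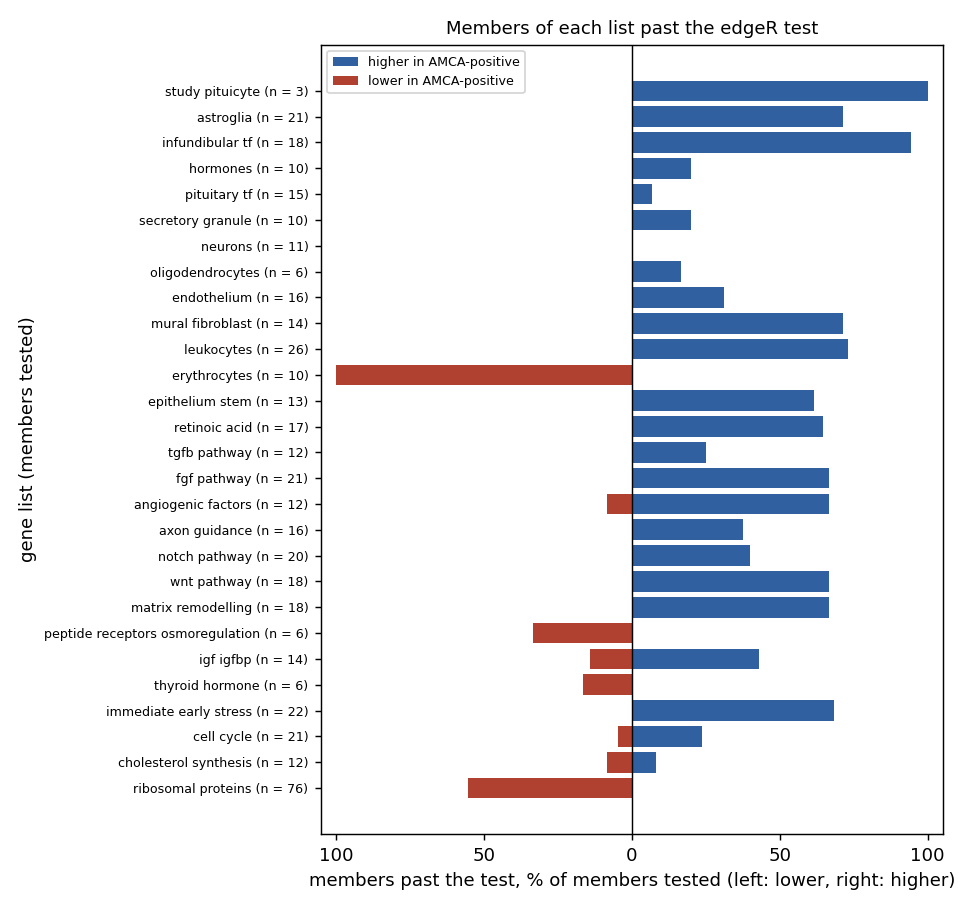
Each bar gives the percentage of a list's tested members that passed the edgeR test as higher (right, blue) or lower (left, red) in AMCA-positive libraries, with the number tested beside the name. The red cell list lies wholly to the left, and 17 of 18 infundibular and 19 of 26 leukocyte markers lie to the right.

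Of the 28 lists with at least 3 tested members, 16 passed limma camera with its preset correlation, 14 up and 2 down, and 3 of them (mural and fibroblast, FGF, matrix) passed with an estimated correlation. As many lists or more passed in 14 of 100 splits of the libraries into groups of 5, the real one included. Of the 13 others, 10 kept 4 libraries of a real group together (10 of 22 such splits) and so share much of the real contrast, and 3 were mixed more evenly (3 of 77). The median log2 fold change of all genes tested was 0.69, which DESeq2 scaling moved by 0.16, scaling from genes outside the red cell list by -0.11 and library size alone by 0.50. With library size alone as scaling, a setting chosen after seeing the data, 2081 genes were higher and 389 lower, so that 84.3% of calls were higher against 71.1%. Without negative replicates 1 and 3, also chosen afterwards, the counts were 1574 and 770. In the authors' deposited table, 2509 genes were higher and 937 lower, of which 1652 and 648 were also called here, with 0 in opposite directions. Every library of one group lay above every library of the other for 24.4% of genes tested, against 0.79% by chance.

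The second comparison asked whether the contrast between the groups differed between plates. No gene passed, and the smallest p were those of hsd11b2, the gene of a cortisol-inactivating enzyme (log2 difference, plate 2 minus plate 1, 10.87 ± 1.22 SE), the oxysterol synthesis gene ch25h (-9.91 ± 1.30) and gmfb (-7.82 ± 1.14), with an edgeR Benjamini-Hochberg adjusted p of 0.156. Of 11150 genes tested, 0 passed by edgeR and DESeq2 called 539. By edgeR 1076 (9.65%) had an unadjusted p under 0.05, more than the share of 0.05 expected if no gene differed and genes were independent. Without positive replicate 1 or 2 that share was 5.00% or 4.36%, and without negative replicate 4 it was 13.2%. The excess therefore depended on single libraries. The simulated interaction recovered 80% of genes at a log2 difference of 16, and smaller differences were not simulated. The lack of calls therefore does not show that the plates gave the same contrast. Without negative replicate 2 edgeR called 179 genes and without negative replicate 5 it called 2. Within plate 1 alone, 29 genes were higher and 34 lower (2 libraries per group), and within plate 2 alone 1411 and 492 (3 per group), counts which also reflect the number of libraries.

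The third comparison set shares of counts per library side by side, as a measure of which cells the libraries held. Red cell genes took 0.0715 ± 0.0379% of counts in AMCA-positive and 24.98 ± 6.91% in AMCA-negative libraries (SD, n = 5; exact two-sided permutation p = 0.00794, the smallest 5 against 5 can give, Benjamini-Hochberg adjusted p = 0.0127). The same exact permutation p and adjusted p were found for the higher shares of immediate early genes (5.09 ± 0.660% against 1.02 ± 0.501%), leukocyte markers (2.57 ± 0.749% against 0.134 ± 0.0897%), astroglial markers (1.04 ± 0.300% against 0.0895 ± 0.0365%) and mural and fibroblast markers (0.115 ± 0.0364% against 0.00621 ± 0.00636%; SD, n = 5). Endothelial markers had 0.0219 ± 0.00505% against 0.0105 ± 0.00921% (exact permutation p = 0.0556, adjusted p = 0.0741). It passed when permuted within plates (adjusted p = 0.0222) and without positive replicate 2 or negative replicate 5 (exact permutation, adjusted p = 0.0423 each). Hormone genes had 2.41 ± 1.11% against 1.72 ± 1.72% (exact permutation p = 0.468) and ribosomal protein genes 11.3 ± 0.872% against 11.9 ± 2.34% (exact permutation p = 0.667), neither different beyond the spread. The hormone share averaged 2.53% against 3.02% on plate 1 and 2.33% against 0.858% on plate 2, and its difference ran from 0.307 to 1.40 points without 1 library. Within plate 1 the red cell share averaged 0.0456% against 22.5% and within plate 2 0.0888% against 26.6%. Leukocyte markers averaged 2.22% against 0.0760% on plate 1 and 2.81% against 0.172% on plate 2.

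**Figure D3:**
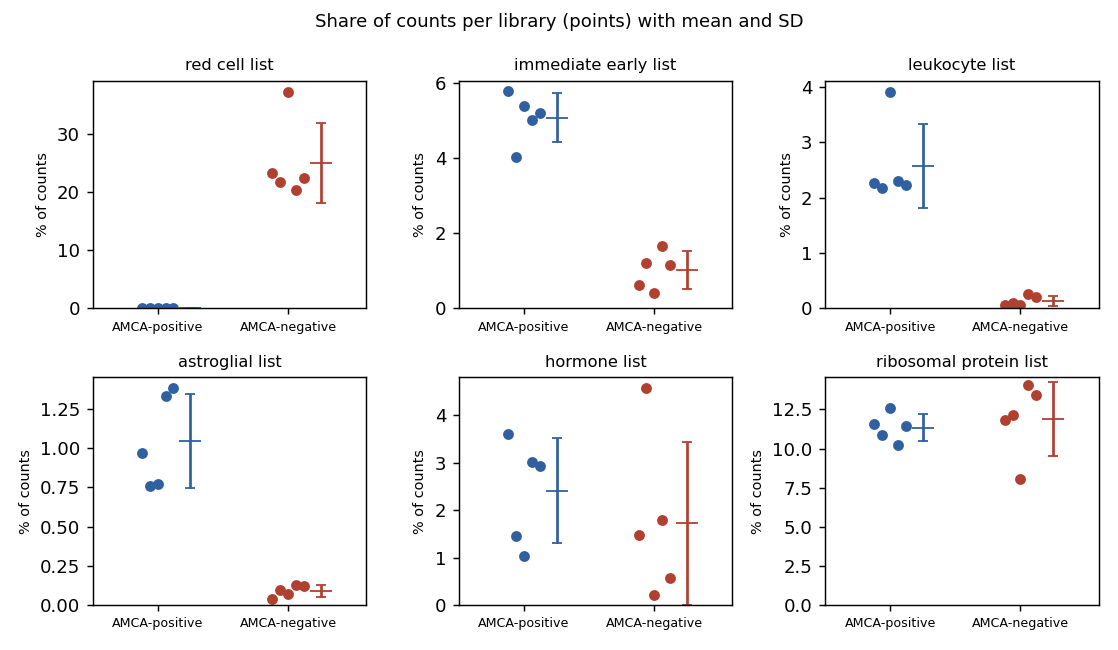
Each panel plots the percentage of a library's counts taken by one gene list, with points for the 5 libraries of a group and a mark with a bar for mean and SD. Red cell shares of the AMCA-negative libraries run from 20.3% to 37.2%, and those of the AMCA-positive libraries stay under 0.13%.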

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

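The tests on genes missing from 1 library, on pomca levels and on the second set of genes of pomca-expressing cells were chosen after the results they bear on were seen. A library far from the other 4 of its group was looked for in 288 groups of 5 values: 51 were found, 13 in AMCA-positive and 38 in AMCA-negative libraries. Normally spread values would give about 1 in 20 or 14.4, a rate that does not hold for genes near 0 counts. In 28 of the AMCA-negative cases the other 4 libraries had no count of the gene, so that any count was flagged. Groups without any count, which cannot be flagged, were among the 288. The excess over 14.4 is therefore no result in itself. Library measures that stood apart were the top 10 genes of negative replicate 3 (47.0% of counts, next 32.4%), its red cell share (37.2%, next 23.2%) and the leukocyte share of positive replicate 3 (3.91%, next 2.29%).

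Among AMCA-positive libraries 1 library was far above the next in CPM of pglyrp5 (627 against 46.4), krt5 (228 against 31.5), rfesd (2.22 against 0.331), nmt1b (3.66 against 0.165), aplnrb (0.496 against 0), pomcb (4.89 against 2.07), igfbp1a (139 against 65.5). One was far below the next in pttg1ipb (22.3 against 62.1), lgals3bpb (444 against 822), epor (0 against 0.148), pecam1 (3.97 against 15.0), mcm3 (3.31 against 11.5). Among AMCA-negative libraries, 1 differed from the next in tbx2a (1.41 against 0.188), slc15a2 (14.7 against 0.439), six1a (15.9 against 0.282), cldnk (36.7 against 0.282), mfap4 (1.69 against 0.245), cxcl12a (0 against 0.188), igf2b (2.25 against 0.220), dio1 (8.58 against 0.245) CPM. The CPM of genes counted in 1 AMCA-negative library, with the other 4 at 0, follow. In negative replicate 1 they were crabp2b (0.282), sema3aa (0.282), mmp14b (0.563), mcm5 (0.563). In negative replicate 2 they were smtla (2.196), chga (8.79), stmn2b (3.29), mpz (0.220), sox7 (0.220), spred1 (0.220), igf2a (0.659), nsdhl (7.91). In negative replicate 3 they were mmp13a (0.245), sox3 (0.245), nkx2.1 (0.245), sfrp1b (0.245). In negative replicate 4 they were erg (0.188), col1a1a (0.376). In negative replicate 5 they were pomcb (0.200), gad1b (2.59), pecam1 (0.599), lum (0.200), robo1 (0.200), fzd2 (0.200), trpv4 (2.39), mcm3 (0.200), aurkb (0.200), gfap (0.200).

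AMCA-positive libraries had more genes with counts than AMCA-negative ones, and this was weighed against the red cell counts. With every library thinned to 3263296 counts outside the red cell list, the lowest AMCA-positive library still had 2251 more genes than the highest AMCA-negative one, which argues against fewer counts left for other genes as the whole cause. Genes of at least 50 CPM in a group were missing from 1 or more of its libraries 142 times as often in the AMCA-negative (144 of 2516) as in the AMCA-positive group (1 of 2481). Few cells other than red cells behind each AMCA-negative library could give this, a hypothesis that leaves a difference between the cell populations open.

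Leukocyte markers rose in AMCA-positive libraries, and the sort named in the labels has no step against leukocytes. Scaling from genes outside the red cell list left 19 leukocyte markers higher. That scaling moved the log2 fold changes by a median of -0.11, beside a median of 4.53 for the leukocyte list. A shift so small could hardly change the number of markers called, so the number decides nothing. The size of the shift argues against RNA of the 10 red cell list genes in the scaling as the whole cause. Red cell RNA of genes outside that list stayed in the scaling and was not tested. Of a second myeloid set sharing no gene with the fixed lists, 50% of 20 tested genes were higher and 1, cxcr4b, lower, against 16.2% higher of all genes tested. The value lies between the bounds set for and against myeloid cells in the AMCA-positive gate, so that this explanation remains open. One leukocyte gene, c1qb, stood at 2277 CPM, and dye uptake by leukocytes and leukocyte genes in the dye-taking cells themselves could not be told apart here.

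The hormone gene pomca was higher in AMCA-positive libraries. Its lowest AMCA-positive level was 62.2 times its highest AMCA-negative level, a value that restates the difference already seen. RNA freed from broken hormone cells and spread evenly through a suspension would give like levels in both gates, so it is not the whole difference; RNA held unevenly by the cells was not tested. In a second set of genes of pomca-expressing cells, of which 6 of 10 tested were also in the fixed lists, 10% were higher, namely the convertase gene pcsk1, and nr3c1 was lower. The bound for that test was set after pcsk1 was known to be higher, so its outcome decides nothing, and of all genes tested 16.2% were higher. Whether pomca-expressing endocrine cells were in the AMCA-positive gate remains open.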

How the results depend on the processing

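Leaving out negative replicates 1 and 3 together, scaling outside the red cell list, upper quartile scaling and library size alone were chosen after seeing the data. Against 2380 called genes (1693 higher, 687 lower), a filter of 10 CPM gave 1418 of 6505 tested (676 higher, 742 lower), which turns the balance, the DESeq2 Wald test 3673 (2711 higher) and plate 1 alone 63 (29 higher, 34 lower) from fewer libraries. Limma-voom with quality weights gave 3283 (2522 higher). It called 13 leukocyte markers higher and 1 lower against 19 and 0. Of retinoic acid genes it called 8 higher against 11, and of mural and fibroblast genes 13 against 10. Library size alone as scaling gave 389 lower genes. With neighbouring wells as a replicate block 438 were lower; the correlation of neighbouring wells' deviations was 0.0054 to 0.035, the best partner in 2 of 5 cases, so the wells are not shown to pair. Leaving out 1 library gave 1761 to 2439 genes (1273 to 1744 higher, 488 to 749 lower). Camera with an estimated correlation passed 3 of 28 lists against 16, and leaving out 1 library 15 to 18. For the pituitary transcription factors camera, which compares a list with other genes, leaned down without passing. The fry test of a list against no change gave the direction up (fry adjusted p = 0.0130), as for 21 of the 23 lists it passed. The interaction gave 0 genes, 539 with DESeq2, and 0 to 179 leaving out 1 library (179 without negative replicate 2, 2 without negative replicate 5). The endothelial share difference, 0.0114 points, passed with permutation within plates and ranged from 0.00912 to 0.0144 leaving out 1 library, passing at 0.0133 without positive replicate 2 and at 0.0144 without negative replicate 5. The causes of these differences were not tested except where stated. Of the values of named genes under alternatives, 2949 kept their side of the threshold, 134 lost it and 39 gained it; for lists 412 kept it, 22 lost it, 13 gained it and 1, that fry result, had the other sign. Mitochondrial genes are not listed, so their removal gave no share. At this depth, with the same dispersion in both simulated groups, 30% of simulated changes of 4 on the log2 scale were recovered.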

Other observations

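Genes not taken by the rule for named genes, chosen after their values were seen, add to the account of AMCA-positive cells. Of these, apoeb is in the astroglial list and il1b in the leukocyte list. The brain aromatase gene cyp19a1b, a marker of radial glia in fish, was at 884 ± 378 CPM against 1.68 ± 0.842 (SD, n = 5; log2 fold change 8.93 ± 0.55 SE, edgeR adjusted p = 2.19e-06), and tac3b, which encodes neurokinin B, was at 260 ± 199 against 0.0776 ± 0.106. The iron-regulating hormone gene hamp was at 667 ± 621 against 1.08 ± 2.08 CPM and the interleukin gene il1b at 912 ± 1250 against 14.0 ± 19.2. The chemokine gene ccl25b was at 2732 ± 1717 against 4.51 ± 7.78 CPM, the complement factor D gene cfd at 4043 ± 2114 against 3.92 ± 5.30 and apoeb at 2531 ± 562 against 11.2 ± 20.5. The edgeR Benjamini-Hochberg adjusted p of these genes ranged from 2.19e-06 (cyp19a1b) to 0.0279 (il1b).

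Hypotheses of secretion were tested on the deposited annotation, with bounds set before the result was seen. Of 495 tested genes placed in the extracellular space, 165 (33.3%) were higher in AMCA-positive cells against 14.2% of other annotated genes, an odds ratio of 3.03 (Fisher's exact test, adjusted p = 1.44e-23 over 38 tests). Growth factor annotations gave 28 of 59 genes higher, 47.5% against 15.06%, an odds ratio of 5.09 (Fisher's exact test, adjusted p = 4.68e-08). Fisher's test counts genes as independent, while genes of one cell type can move together across the 10 libraries. All p values from it here therefore overstate the certainty, and the percentages are the safer reading. Terms without preset bounds were also enriched: plasma membrane (26.1% higher against 13.7%, odds ratio 2.22, adjusted p = 8.83e-22), transmembrane receptor (odds ratio 2.97, adjusted p = 7.50e-07) and G-protein coupled receptor (odds ratio 2.67, adjusted p = 3.12e-04; Fisher's exact test), so the enrichment is not specific to secretion. This may be a property of dye-taking cells or of any other cell type set against red cells, which the enrichment does not separate.

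Splits of the libraries into other groups of 5 tested chance. Among 100 splits, 1 gave as many called genes, the real one itself (2380, highest other 0). Every other split puts libraries of both real groups into each of its groups. The real contrast then adds to the spread within groups and lowers the calls. The count shows that the called genes follow the dye groups, but its 0 elsewhere is not a clean measure of chance. For lists, 14 of 100 gave 16 or more, the real one included (real 16; highest other 20), so by this count chance cannot be excluded for the number of lists passed. The count is not a clean measure of chance, since 10 of the 13 others kept 4 libraries of a real group together. Of the 77 other splits mixed more evenly, 3 gave 16 or more, with a median of 4 and a highest of 20.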
